A study of Mus musculus with 24 samples.

How the data were processed

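Total RNA from mouse liver was extracted with Trizol, purified, turned into cDNA and labelled with Cy5 in 24 samples, and a reference RNA was labelled with Cy3, per the labels' protocols. The labels name the reference as a commercial RNA from assorted mouse tissues, while the fields of the same channel also name liver, so its makeup is uncertain. Each sample was hybridized with the reference on 1 Agilent 2-colour array. The labels do not state that the replicates of a group come from separate animals, so p-values measure only the spread between these samples.

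The spot intensities were read by the scanner software Agilent Feature Extraction 11.5.1.1, which, per the file headers, gave a median spot intensity and a median local background intensity in both channels and processed intensities that are background-subtracted, spatially detrended and dye-normalized. The files hold no mean spot signal, so the median was used. The deposited log10 ratios of Cy5 over Cy3 were made by the same software from its processed intensities, per the file headers. The deposited table of log2 values held the log2 ratio of processed Cy5 over Cy3, with the spots of a probe averaged, since each of its columns followed that ratio of the sample's own file with a slope of 1.00. The headers of that table do not state how it was made.

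The values were computed again from the median intensities. Spots that the software marked as non-uniform or as population outliers in either channel were left out, which were 1.34% to 7.64% of the spots of an array. Background was corrected with normexp (offset 50) and each array was normalized by loess within the array, with no scaling between arrays, in limma 3.58.1 under R 4.3.3, with statmod 1.5.0, MASS 7.3.60.0.1 and version 1.17.8 of data.table. Replicate spots of the 245 probes that have them were averaged. Of 41174 non-control probes, 36618 were well above background in Cy5 on at least 3 arrays and were kept. The files pair probes with accessions, and 27816 probes matched exactly 1 symbol in the gene names given for the GRCm38.p6 assembly, which was used for names only. Probes with no match are unnamed here, not without a gene. Of the kept probes 26000 had a name, which gave 17855 genes. For each of the 6197 genes with more than 1 kept probe the brightest probe measured on at least 2 arrays of every group was used. Leaving out marked spots and requiring 2 arrays of every group were decided after the data were seen, and the alternatives without them are listed with the others. A comparison tested the genes measured on at least 2 arrays of each of its groups, and 16820 genes could be tested in every group. No array was left out, 0 spots were saturated and 0 pairs of arrays were identical.

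The groups came from the labels. One fit of the 6 group means over all 24 arrays in limma, with empirical Bayes moderation, gave 9 comparisons, and a gene was called where its Benjamini-Hochberg adjusted p was under 0.05. The last of the 9 comparisons was the difference of 2 effects, tested as an interaction. All adjusted p-values of genes come from limma. The comparisons, the fit, the rule for the genes named, the gene lists and the main alternatives were chosen before the data were examined. The rule named Cidec in every comparison. For comparisons with pair-fed groups and for the single binge against the long diet alone, it added the 6 largest rises and the 6 largest falls among called genes, and for the other comparisons 3 and 3. These genes had every array of the first group on one side of the second group's mean, which favours one sign across slides. All were well above background in Cy5 on every array of the higher group. For the interaction this background rule was applied to every array of both binge groups. For each list described, up to 4 members with the lowest adjusted p that passed and up to 2 others that did not pass were named. Which lists are described under which comparison was chosen after the list results were seen. The text gives part of these genes in full, and the results of some genes, also left out of the scan for outlying arrays, are not reported here.

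The 26 gene lists were written from general knowledge of liver biology, not chosen on these samples. They were tested with camera, which compares a list with the other genes, at its preset correlation of 0.01 and with an estimated correlation, and with fry, which tests whether the genes of a list move, on balance, one way. P-values were adjusted over all 234 pairs of list and comparison. Of these pairs 80 passed camera at the preset correlation, 0 passed with the estimated correlation and 84 passed fry. The median, the mean and the direction of the test differed in sign in 35 pairs, 0 of which passed camera. Genes of the lists without a matched probe that passed the filter were not analysed here, and these were Acss1, Cyp2c50, Slco1a1, Pck1, Irs2, Cxcl5, Il6, Mx1, Mx2, Ly6g, Cd68, Gpnmb, Gzmb, Lox, Aurkb, Ccnd1, Rrm2, Mup20, Sult2a1, Sult3a1, A1bg, Hbb-b1 and Hbb-b2.

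The file headers placed the arrays on 11 slides and in 3 scans. The slide was entered as a block where a comparison lay within a scan. The Cy3 channel alone was fitted in the same way, since a reference that is the same on all arrays should call no genes. In limma it called 0 genes for 10 days of ethanol plus a binge against pair-feeding (451 at an unadjusted p under 0.05), 0 for 8 weeks of ethanol against pair-feeding (384) and 0 for the interaction (551). It called 1 gene for 8 weeks of ethanol plus a binge against pair-feeding and 1 against 8 weeks of ethanol alone. In both it was Mt1, the largest rise of these comparisons, at -1.63 (adjusted p = 0.0258) and -1.55 (adjusted p = 0.0231). No comparison had every pair of same-numbered arrays correlated above 0.1 in deviations from group means, so the numbers were not taken as pairs.

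The fit was tested on simulated data for 16820 genes with known log2 changes of 0.5, 1 and 2. It recovered 55.2%, 95.5% and 100% of them for 10 days of ethanol plus a binge against pair-feeding. For 8 weeks of ethanol against pair-feeding it recovered 58.2%, 98.5% and 100%, for 8 weeks of ethanol plus a binge against pair-feeding 68.7%, 97.0% and 100%, and for the interaction 13.4%, 83.6% and 97.0%.

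The alternatives were other normalizations within and between arrays, another offset, the scanner software's log ratio, the deposited log2 table, Cy5 alone, other filters on dim probes, blocks for the slide, the scan and the replicate number, fits of the compared groups alone, a trended and robust variance, array weights, the mean of all probes of a gene, and leaving out each array. Alternatives chosen after seeing the data were keeping the marked spots, taking the brightest probe whatever its marks, and leaving out the 3 arrays of slide 5, whose reference differed from that of slides 1 to 4.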

Results

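Gene expression was measured in livers of male mice of the inbred strain C57BL/6N on 24 Agilent 2-colour arrays, 1 array per sample. Liver RNA was labelled with Cy5 and a common reference RNA with Cy3, so that each value is the level of a transcript in a liver relative to the reference on the same array. The labels give 6 groups. Pair-fed mice, which received a control diet in the amount eaten by ethanol-fed animals, were sampled after 8 weeks (n = 4) or 10 days (n = 3). Ethanol-fed mice were sampled after 8 weeks without a binge (n = 5), after 10 days with 1 binge (n = 3) and after 8 weeks with 1 binge (n = 5). A further group had 8 weeks of ethanol with multiple binges, given 2 times per week (n = 4). A binge was a single dose of 5 g of ethanol per kg. The median Cy5 signal per array lay between 95.5 and 247 intensity units and that of Cy3 between 161.5 and 505. Of the probes, 70.4% to 86.7% were well above background in Cy5. The number of arrays limits the precision of every value reported. Scan 1 held the 8-week pair-fed, ethanol and single-binge groups, scan 2 both 10-day groups, and scan 3 the multiple-binge group alone. The Cy3 reference correlated across genes at a median r of 0.984 (lowest 0.948) between arrays of scan 1. The median was 0.975 between scans 1 and 2 and 0.913 between scans 1 and 3. Genes are not independent replicates in these correlations.

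Cidec encodes fat-specific protein 27, also called CIDEC, which promotes the growth of lipid droplets and is named in the title of the series. The first question was in which feeding group its transcript differed from the controls. Cidec rose after 8 weeks of ethanol with 1 binge, by 3.25 ± 0.64 (log2 fold change ± SE, n = 5 and 4 arrays, adjusted p = 0.00091) against 8-week pair-fed mice. Against 8 weeks of ethanol alone it rose by 3.19 ± 0.60 (n = 5 and 5, adjusted p = 0.000592). The single-binge arrays lay between 0.22 and 2.07 (log2 Cy5/Cy3), the 8-week pair-fed arrays between -2.91 and -0.73, and the ethanol arrays without a binge between -3.14 and -0.93. With the slide as a block these differences were 3.25 (adjusted p = 0.00134) and 3.19 (adjusted p = 0.000645). Cidec was higher on each of the 4 and 5 slides that held both groups.

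Without a binge, 8 weeks of ethanol gave a Cidec difference of 0.05 ± 0.64 (adjusted p = 0.998, slide-blocked 0.06). This value was -0.25, -0.12 and -0.20 without pair-fed replicate 2, pair-fed replicate 3 and ethanol replicate 1. After 10 days of ethanol with a binge the difference was 0.65 ± 0.77 (n = 3 and 3, adjusted p = 0.745, slide-blocked 1.42), and it was -0.073 without binge replicate 3 and 1.83 without binge replicate 1. That array had Cidec at -2.40 (log2 Cy5/Cy3) against 0.84 and 1.41 on the other 2. After multiple binges Cidec differed by 1.80 ± 0.67 (n = 4 and 4, adjusted p = 0.0588) from pair-fed mice. That difference passed the test without pair-fed replicate 1 (adjusted p = 0.0276) or multiple-binge replicate 2 (adjusted p = 0.0383), in Cy5 alone, in a fit of these groups alone and with array weights. Against 8 weeks of ethanol alone Cidec rose by 1.74 ± 0.64 (n = 4 and 5, adjusted p = 0.0464). This call was lost without ethanol replicates 2, 3, 4 or 5 (adjusted p = 0.12, 0.0707, 0.0691 and 0.0583) or multiple-binge replicates 1 or 3 (0.141 and 0.153). It was also lost under 7 other settings, median centring and the scanner software's log ratio among them.

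Multiple binges against a single binge gave a Cidec difference of -1.45 ± 0.64 (n = 4 and 5, adjusted p = 0.0879), which passed with median centring and with array weights. The pair-fed groups differed by -1.29 ± 0.72 in the ratio (8 weeks minus 10 days, n = 4 and 3, adjusted p = 0.407) and by 0.11 in Cy5 alone. The 8-week effect of ethanol with a binge minus the 10-day effect was 2.59 ± 1.00 (adjusted p = 0.188, slide-blocked 1.83). It was 1.42 without 10-day binge replicate 1 and 3.32 without replicate 3.

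**Figure D1:**
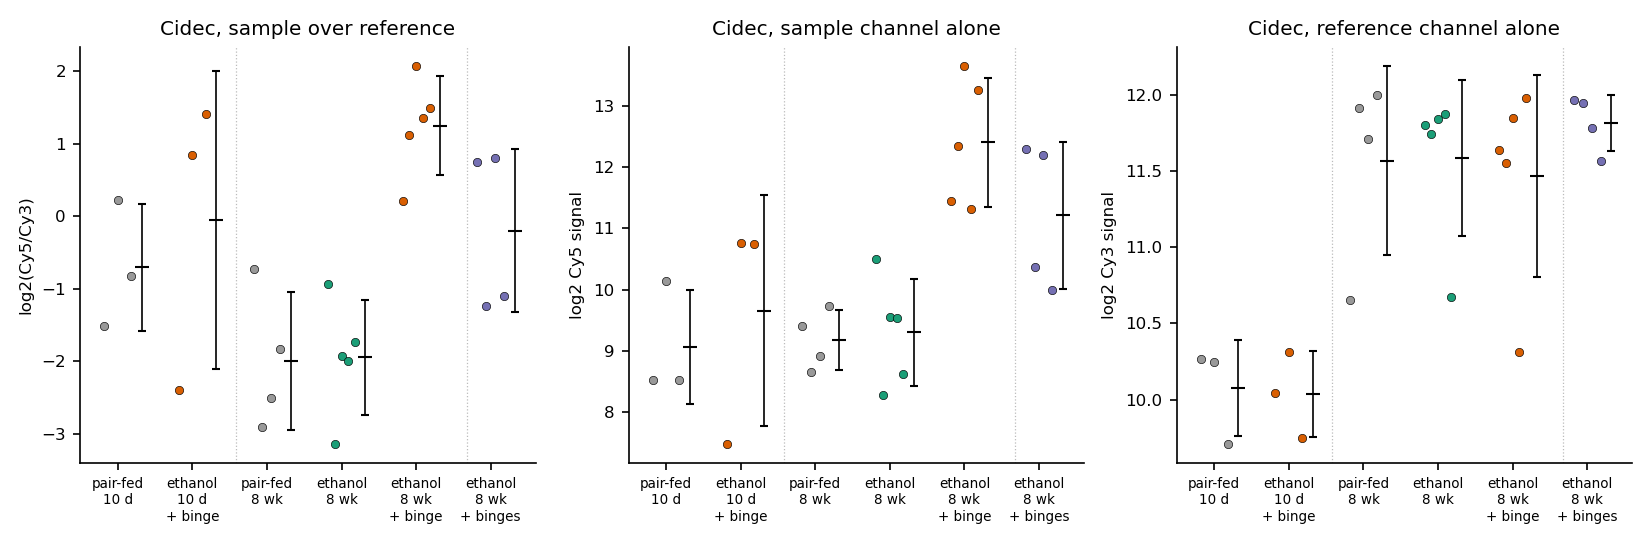
Cidec on each array by group, as the log2 Cy5/Cy3 ratio, as log2 Cy5 intensity alone and as log2 Cy3 intensity alone, with points for arrays, bars for the group mean with SD, and dotted lines between scans. The 5 single-binge arrays lie between 0.22 and 2.07 in the ratio, and Cy3 differs between scans and on slide 5.

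The comparison of 10 days of ethanol plus 1 binge with 10-day pair-feeding (n = 3 and 3) asked what the short diet with a binge changed in the liver. Acute phase genes, whose products the liver secretes in inflammation, were among the largest rises, and fatty acid omega-hydroxylase genes among the largest falls. Saa3, a serum amyloid A gene, rose by 5.11 ± 1.27 (log2 fold change ± SE, adjusted p = 0.0139). Lcn2, which encodes the iron-withholding protein lipocalin 2, rose by 4.34 ± 0.94 (adjusted p = 0.00529). The omega-hydroxylase gene Cyp4a14, a target of PPAR-alpha, fell by 4.62 ± 0.72 (adjusted p = 0.000247), its relative Cyp4a10 fell by 4.05 ± 0.27 (adjusted p = 1.7e-05) and Cyp4a31 fell by 3.45 ± 0.32 (adjusted p = 1.5e-06). Cyp2c70, which makes muricholic acids in mice, rose by 3.68 ± 0.55 (adjusted p = 0.00021). Cyp2b10, a target of the xenobiotic receptor CAR, rose by 3.99 ± 0.68 (n = 2 and 3, adjusted p = 0.00101). Etnppl, an ethanolamine-phosphate lyase, fell by 2.78 ± 0.37 and Map2k6, a kinase that activates p38, fell by 2.48 ± 0.28. With the slide as a block Lcn2 was at 5.67, Cyp4a14 at -4.88, Cyp4a31 at -3.84, Cyp2c70 at 3.57, Etnppl at -3.09 and Map2k6 at -2.44. Each of the 6 had the same sign on both slides that held both groups. The Saa3 call was lost without binge replicate 2 (adjusted p = 0.0885) or 3 (adjusted p = 0.0853), and in Cy5 alone, where Saa3 was at 3.74 (adjusted p = 0.0539, Cy3 -1.31). The slide-blocked value of Saa3 was 6.75. Cyp4a10 was at -3.09 in Cy5 alone (Cy3 1.41). Binge replicate 1 stood apart, with Saa3 at -2.48 (log2 Cy5/Cy3) against 1.60 and 2.20 on the other binge arrays and Lcn2 at -2.46 against 1.12 and 1.40. Without it Saa3 was at 6.58 and Lcn2 at 5.58, and without binge replicate 3 Lcn2 was at 3.65. Replicate 1 lay on a slide without a pair-fed array, so the 2 slides that held both groups leave it out.

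Of 21 genes of fatty acid oxidation and PPAR-alpha 1 rose and 12 fell (1 higher and 13 lower adjusted over the list alone). The fatty acid oxidation list had a median of -0.64 (slide-blocked -0.64, negative on 2 of 2 slides) and passed camera (adjusted p = 3.78e-09, but adjusted p = 0.238 with an estimated correlation). Cpt1a, which admits fatty acids to mitochondria, fell by 0.96 ± 0.16 and Hadhb, a subunit of the mitochondrial trifunctional protein, fell by 0.74 ± 0.11. Of 20 acute phase genes 12 rose (16 higher adjusted over the list alone). The acute phase list had a median of 1.90 (slide-blocked 2.39, positive on 2 of 2 slides) and passed camera (adjusted p = 1.23e-08, but adjusted p = 0.324 with an estimated correlation). Binge replicate 1 is on neither of the 2 slides. Of 19 endoplasmic reticulum stress genes 9 rose (11 higher adjusted over the list alone). The endoplasmic reticulum stress list had a median of 0.85 (slide-blocked 0.85, positive on 2 of 2 slides) and passed camera (adjusted p = 0.000172, but adjusted p = 0.265 with an estimated correlation). Among the stress genes Creld2, which encodes a folding factor, rose by 2.58 ± 0.50 (1.77 without binge replicate 2) and Edem1, which targets misfolded glycoproteins for degradation, by 0.85 ± 0.12. Of 19 antioxidant and glutathione genes 4 rose (7 higher adjusted over the list alone). The antioxidant list had a median of 0.38 (slide-blocked 0.84, positive on 2 of 2 slides) and passed camera (adjusted p = 9.16e-05, but adjusted p = 0.265 with an estimated correlation). The metallothionein gene Mt1 rose by 2.82 ± 0.60 in the ratio and was at 1.60 in Cy5 alone, and its Cy3 signal differed by -0.95. Of 20 genes of fatty acid and triglyceride synthesis 4 rose and 1 fell (5 higher and 1 lower adjusted over the list alone). The fatty acid synthesis list had a median of 0.53 (slide-blocked 0.11, positive on 2 of 2 slides) and passed camera (adjusted p = 0.0193, but adjusted p = 0.513 with an estimated correlation). Thrsp, a regulator of lipogenesis, rose by 3.30 ± 0.37 (3.92 without pair-fed replicate 3). In Cy5 alone Hadhb and Edem1 did not pass (adjusted p between 0.0539 and 0.0724).

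Of 12 endothelial cell markers 4 rose (6 higher adjusted over the list alone). The endothelial list had a median of 0.38 (slide-blocked 0.34, positive on 2 of 2 slides) and passed camera (adjusted p = 0.000524, but adjusted p = 0.313 with an estimated correlation). Fcgr2b, an Fc receptor of sinusoidal endothelium, rose by 1.04 ± 0.21 (slide-blocked 1.13). Of 16 clock genes 3 rose and 5 fell (3 higher and 7 lower adjusted over the list alone). The clock gene list had a median of -0.24 (slide-blocked -0.26, negative on 2 of 2 slides) and did not pass camera (adjusted p = 0.0712). The clock output gene Dbp fell by 2.25 ± 0.37 (n = 2 and 3). Of 11 female-predominant liver genes 2 fell (5 lower adjusted over the list alone). The female-predominant list had a median of -0.46 (slide-blocked -0.45, negative on 2 of 2 slides) and passed camera (adjusted p = 0.000291, but adjusted p = 0.234 with an estimated correlation). Of 16 bile acid genes 1 rose and 1 fell (1 higher and 1 lower adjusted over the list alone). The bile acid list had a median of -0.31 (slide-blocked -0.35, negative on 2 of 2 slides) and passed camera (adjusted p = 0.0181, but adjusted p = 0.313 with an estimated correlation). Over all genes, 723 of 17355 rose and 488 fell, 197 and 58 of them by at least 2-fold. The total of 1211 became 555 with the slide as a block, 498 of them shared, 403 with median centring (73.0% higher against 59.7%), 306 in Cy5 alone and 1872 with array weights. It became 636 and 735 without pair-fed replicates 1 and 2 and 590 without binge replicate 2.

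The comparison of 8 weeks of ethanol with 8-week pair-feeding (n = 5 and 4) asked what the long diet changed without a binge. Few genes passed, among them cytochrome P450 genes of xenobiotic metabolism. Cyp2b9, a P450 that is higher in female than in male mouse liver, rose by 3.27 ± 0.42 (log2 fold change ± SE, adjusted p = 0.00168) and was higher on each of the 4 slides that held both groups. Gadd45g, a growth arrest gene, fell by 2.32 ± 0.36 (adjusted p = 0.0046, slide-blocked -2.53). The inducible heat shock gene Hspa1a fell by 1.41 ± 0.19 (adjusted p = 0.00168, slide-blocked -1.32) and was well above background in Cy5 on 2 of 5 ethanol arrays. Dct, known for its role in melanin synthesis, fell by 1.17 ± 0.17 (adjusted p = 0.00214, slide-blocked -1.13), and the other of its 2 probes was at 0.04. These 3 genes were lower on all 4 slides. A further 9 named genes passed. They were Cyp2b13 (log2 fold change 2.14 ± 0.37), Cyp2c29 (1.68 ± 0.30, n = 4 and 3), Cyp3a16 (1.41 ± 0.23, n = 2 and 3), Depp1 (1.64 ± 0.30), Tnfaip2 (0.84 ± 0.17), Plk3 (-1.73 ± 0.34), Slc10a2 (-1.42 ± 0.25), Coq10b (-1.10 ± 0.18) and the glutathione transferase gene Gsta4 (0.62 ± 0.10). Each of the 9 lost its call without pair-fed replicate 2 (adjusted p between 0.0553 and 0.154). Some of these 9 calls were also lost without pair-fed replicates 1, 3 or 4 (highest adjusted p = 0.0728, 0.16 and 0.116). Some were lost without ethanol replicates 1, 2, 3, 4 or 5 (0.0849, 0.161, 0.108, 0.0732 and 0.0758). Cyp2c29, Tnfaip2 and Plk3 did not pass with the slide as a block (adjusted p = 0.25, 0.179 and 0.0764), and in Cy5 alone Cyp2b13, Cyp2c29, Cyp3a16 and Gsta4 did not (adjusted p between 0.0713 and 0.425).

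Of 12 xenobiotic metabolism genes 3 rose (8 higher adjusted over the list alone). The xenobiotic list had a median of 0.89 (slide-blocked 1.19, positive on 4 of 4 slides) and passed camera (adjusted p = 3.78e-09, but adjusted p = 0.089 with an estimated correlation). Its members that rose were Cyp2b9, Cyp2b13 and Cyp2c29. Of 12 female-predominant liver genes 3 rose (6 higher adjusted over the list alone). The female-predominant list had a median of 0.50 (slide-blocked 0.28, positive on 3 of 4 slides) and passed camera (adjusted p = 1.61e-06, but adjusted p = 0.089 with an estimated correlation). Of its members, Cyp2b9 and Cyp2b13 were also on the xenobiotic list. Of 19 antioxidant and glutathione genes 1 rose (3 higher adjusted over the list alone). The antioxidant list had a median of 0.30 (slide-blocked 0.62, positive on 3 of 4 slides) and passed camera (adjusted p = 3.32e-05, but adjusted p = 0.265 with an estimated correlation). Of 12 gluconeogenesis, fasting and glucocorticoid genes 0 passed in limma over all genes (2 lower adjusted over the list alone), with 5 lower at an unadjusted p under 0.05. The gluconeogenesis and fasting list had a median of -0.29 (slide-blocked -0.40, negative on 4 of 4 slides) and passed camera (adjusted p = 2.53e-05, but adjusted p = 0.089 with an estimated correlation). Of 15 clock genes 0 passed in limma over all genes (4 lower adjusted over the list alone), with 5 lower at an unadjusted p under 0.05. The clock gene list had a median of -0.09 (slide-blocked -0.10, negative on 4 of 4 slides) and passed camera (adjusted p = 0.00571, but adjusted p = 0.089 with an estimated correlation). Of 19 lipid droplet protein and lipase genes 0 passed in limma over all genes (2 higher adjusted over the list alone), with 2 higher at an unadjusted p under 0.05. The lipid droplet list had a median of 0.17 (slide-blocked 0.18, positive on 4 of 4 slides) and passed camera (adjusted p = 0.00301, but adjusted p = 0.386 with an estimated correlation). In all, 10 of 17368 genes rose and 14 fell, and 1234 had an unadjusted p under 0.05. The total of 24 was 20 with the slide as a block, 13 of them shared and 55.0% higher against 41.7%, and 43 with it as a random block. It was 12 with median centring, 12 with the scanner software's log ratio, 14 with the deposited values, 11 with the replicate number as a block, 93 with array weights, and 36 with marked spots kept. In Cy5 alone 4 genes were higher and 19 lower. The total was 6, 7 and 36 without pair-fed replicates 2, 3 and 4, and 13, 10 and 13 without ethanol replicates 2, 3 and 4.

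The comparison of 8 weeks of ethanol plus 1 binge with 8-week pair-feeding (n = 5 and 4) asked what the long diet with a binge changed. Metallothionein genes, Lcn2 and the gene of the cell cycle inhibitor p21 were among the largest rises, and a steroid-metabolising enzyme and a clock output gene among the largest falls. Mt1, which encodes a zinc-binding metallothionein, rose by 5.55 ± 0.49 (log2 fold change ± SE, adjusted p = 2.65e-07) and its relative Mt2 by 4.78 ± 0.55 (n = 5 and 3). In Cy5 alone they were at 3.52 and 3.88, since the Cy3 signal of Mt1 differed by -1.63 (adjusted p = 0.0258). Lcn2 rose by 4.22 ± 0.78 (adjusted p = 0.000518), Cdkn1a, which encodes p21, by 4.17 ± 0.54 (adjusted p = 1.39e-05) and the CAR target Cyp2b10 by 3.76 ± 0.50. Cyp2b10 was well above background in Cy5 on 1 of 4 pair-fed arrays. Without binge replicate 2 Lcn2 was at 4.81. Hsd3b5, a 3-ketosteroid reductase of male mouse liver, fell by 4.20 ± 0.58 (adjusted p = 2.55e-05, well above background in Cy5 on 3 of 5 binge arrays) and Dbp fell by 2.97 ± 0.27 (adjusted p = 4.57e-07). Keg1 fell by 2.96 ± 0.39, the replication factor gene Mcm10 fell by 2.89 ± 0.29 and Srebf1, a transcription factor of lipid synthesis, fell by 2.72 ± 0.34. With the slide as a block Mt1 was at 5.37, Lcn2 at 4.04, Cdkn1a at 4.11, Hsd3b5 at -4.01, Dbp at -2.83 and Srebf1 at -2.65, each on the same side on 4 of 4 slides.

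Of 19 lipid droplet protein and lipase genes 9 rose and 1 fell (9 higher and 1 lower adjusted over the list alone). The lipid droplet list had a median of 0.42 (slide-blocked 0.52, positive on 4 of 4 slides) and passed camera (adjusted p = 0.00198, but adjusted p = 0.361 with an estimated correlation). Besides Cidec, the droplet coat gene Plin4 rose by 2.61 ± 0.27, Plin3 by 1.20 ± 0.16 (n = 4 and 3) and Plin5 by 1.17 ± 0.14. Abhd5, a lipase co-activator gene, rose by 0.61 ± 0.10, while Plin1 was at 0.20 ± 0.09 (adjusted p = 0.161). Of 14 PPAR-gamma and adipocyte-type genes 6 rose (6 higher adjusted over the list alone). The PPAR-gamma list had a median of 0.25 (slide-blocked 0.25, positive on 4 of 4 slides) and passed camera (adjusted p = 9.16e-05, but adjusted p = 0.238 with an estimated correlation). The adipocyte fatty acid-binding protein gene Fabp4 rose by 1.21 ± 0.13 (in Cy5 alone 0.78, adjusted p = 0.0568) and the lipoprotein receptor gene Vldlr by 0.86 ± 0.14, and Pparg itself was at 0.22 ± 0.11 (adjusted p = 0.182). Of 19 antioxidant and glutathione genes 11 rose and 1 fell (11 higher and 1 lower adjusted over the list alone). The antioxidant list had a median of 0.76 (slide-blocked 1.16, positive on 4 of 4 slides) and passed camera (adjusted p = 7.67e-09, but adjusted p = 0.108 with an estimated correlation). The glutathione transferase gene Gstm1 rose by 3.05 ± 0.37 (Cy5 1.78, Cy3 -0.76). Of 19 acute phase genes 8 rose and 1 fell (9 higher and 1 lower adjusted over the list alone). The acute phase list had a median of 1.39 (slide-blocked 1.16, positive on 3 of 4 slides) and passed camera (adjusted p = 8.01e-05, but adjusted p = 0.482 with an estimated correlation). Over the slides its median ran from -0.62 to 2.48. Binge replicate 2 had the lowest Saa3, at -4.65 (log2 Cy5/Cy3) against -1.24 to 1.61 on the other binge arrays. Its Serpina3n was at -3.05 against -0.83 on the next. Pair-fed Saa3 lay at -5.43 on replicate 4 and -1.51 to -0.89 on the others. The lipopolysaccharide receptor gene Cd14 rose by 2.30 ± 0.32 and the binding protein gene Lbp by 1.39 ± 0.19 (n = 4 and 4). Of 14 xenobiotic metabolism genes 6 rose (10 higher adjusted over the list alone). The xenobiotic list had a median of 0.93 (slide-blocked 0.84, positive on 4 of 4 slides) and passed camera (adjusted p = 0.0308, but adjusted p = 0.533 with an estimated correlation). Among the P450 genes Cyp2b9 rose by 2.91 ± 0.42.

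Of 14 hepatocyte function genes 5 fell (1 higher and 8 lower adjusted over the list alone). The hepatocyte list had a median of -0.37 (slide-blocked -0.42, negative on 4 of 4 slides) and passed camera (adjusted p = 0.00764, but adjusted p = 0.265 with an estimated correlation). Hpd, an enzyme of tyrosine breakdown, fell by 1.41 ± 0.30 (n = 5 and 3) and the antithrombin gene Serpinc1 fell by 0.49 ± 0.12 (n = 5 and 2, adjusted p = 0.139 in Cy5 alone). Of 12 alcohol and aldehyde metabolism genes 1 rose and 7 fell (2 higher and 7 lower adjusted over the list alone). The alcohol metabolism list had a median of -0.56 (slide-blocked -0.16, negative on 4 of 4 slides) and did not pass camera (adjusted p = 0.177). The alcohol dehydrogenase gene Adh4 fell by 1.95 ± 0.22 and Adh5 fell by 0.61 ± 0.11 (n = 5 and 3 for both). Of 16 clock genes 2 rose and 5 fell (2 higher and 7 lower adjusted over the list alone). The clock gene list had a median of -0.12 (slide-blocked -0.03, negative on 4 of 4 slides) and passed camera (adjusted p = 0.0308, but adjusted p = 0.238 with an estimated correlation). Tef fell by 1.26 ± 0.13 and Per3 fell by 0.82 ± 0.12. Of 11 male-predominant liver genes 3 fell (1 higher and 3 lower adjusted over the list alone). The male-predominant list had a median of -0.18 (slide-blocked -0.16, negative on 4 of 4 slides) and passed camera (adjusted p = 0.0447, but adjusted p = 0.287 with an estimated correlation). Of 14 interferon-stimulated genes 4 fell (5 lower adjusted over the list alone). The interferon list had a median of -0.32 (slide-blocked -0.25, negative on 4 of 4 slides) and passed camera (adjusted p = 0.011, but adjusted p = 0.423 with an estimated correlation). In all, 1218 of 17415 genes rose and 1473 fell, 160 and 162 by at least 2-fold. The total of 2691 was 2138 with the slide as a block, 1955 of them shared, 1279 with median centring and 1731 in a fit of these groups alone. In Cy5 alone it was 1959, with 18.2% higher against 45.3%.

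The comparison of 8 weeks of ethanol plus 1 binge with 8 weeks of ethanol alone (n = 5 and 5) asked what a single binge added to the long diet. Metallothionein genes, Lcn2, Cdkn1a and the immediate early gene Egr1 were among the largest rises. Mt1 rose by 6.12 ± 0.46 (log2 fold change ± SE, adjusted p = 2.33e-08, and 4.29 in Cy5 alone, with Cy3 at -1.55, adjusted p = 0.0231) and Mt2 by 5.31 ± 0.48 (4.50 in Cy5 alone). Lcn2 rose by 4.91 ± 0.73 (adjusted p = 5.2e-05, 5.50 without binge replicate 2), Cdkn1a by 4.41 ± 0.51 and Egr1 by 3.39 ± 0.39 (adjusted p = 3.17e-06). The steroid dehydrogenase gene Hsd3b2 fell by 2.42 ± 0.24 (adjusted p = 6.91e-07), Keg1 fell by 2.87 ± 0.37 and the apolipoprotein L gene Apol7a fell by 2.39 ± 0.25 (n = 5 and 4). The methyltransferase gene Inmt fell by 2.34 ± 0.21, Srebf1 fell by 2.33 ± 0.32 and Hsd3b5 fell by 2.20 ± 0.55 (well above background in Cy5 on 3 of 5 binge arrays). Each of the 5 slides held 1 array of each group. Slide-blocked differences therefore equal these values by arithmetic, except Apol7a at -2.48. Each gene had the same sign on every slide compared.

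Of 20 acute phase genes 13 rose (16 higher adjusted over the list alone). The acute phase list had a median of 1.38 (slide-blocked 1.38, positive on 4 of 5 slides) and passed camera (adjusted p = 7.67e-09, but adjusted p = 0.314 with an estimated correlation). Over the slides its median ran from -0.42 to 2.31, and binge replicate 2 was lowest for Saa3 and Serpina3n. Of 12 gluconeogenesis, fasting and glucocorticoid genes 8 rose and 2 fell (9 higher and 2 lower adjusted over the list alone). The gluconeogenesis and fasting list had a median of 0.89 (slide-blocked 0.82, positive on 5 of 5 slides) and passed camera (adjusted p = 0.000256, but adjusted p = 0.182 with an estimated correlation). Fkbp5, which glucocorticoids induce, rose by 1.97 ± 0.16 and the fasting hormone gene Fgf21 by 1.31 ± 0.27, whereas G6pc, which encodes the last enzyme of gluconeogenesis, fell by 1.98 ± 0.41 (n = 5 and 4). Of 18 bile acid genes 1 rose and 9 fell (1 higher and 10 lower adjusted over the list alone). The bile acid list had a median of -0.46 (slide-blocked -0.62, negative on 5 of 5 slides) and passed camera (adjusted p = 7.69e-07, but adjusted p = 0.089 with an estimated correlation). Cyp8b1, the sterol 12-alpha-hydroxylase gene, fell by 1.57 ± 0.25 (n = 5 and 3) and Slc27a5, whose product activates bile acids, fell by 0.94 ± 0.12. Of 13 alcohol and aldehyde metabolism genes 1 rose and 7 fell (1 higher and 8 lower adjusted over the list alone). The alcohol metabolism list had a median of -0.50 (slide-blocked -0.49, negative on 5 of 5 slides) and passed camera (adjusted p = 0.00204, but adjusted p = 0.287 with an estimated correlation). Adh4 fell by 2.06 ± 0.20 (n = 5 and 4) and Cyp2e1, an ethanol-oxidising P450 gene, fell by 0.79 ± 0.16.

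Of 23 genes of fatty acid oxidation and PPAR-alpha 2 rose and 8 fell (2 higher and 9 lower adjusted over the list alone). The fatty acid oxidation list had a median of -0.26 (slide-blocked -0.26, negative on 5 of 5 slides) and passed camera (adjusted p = 0.000447, but adjusted p = 0.439 with an estimated correlation). Ppara fell by 1.06 ± 0.18 and Cpt1a fell by 0.55 ± 0.13. Of 18 endoplasmic reticulum stress genes 2 rose (1 higher adjusted over the list alone). The endoplasmic reticulum stress list had a median of 0.53 (slide-blocked 0.53, positive on 5 of 5 slides) and passed camera (adjusted p = 0.000767, but adjusted p = 0.332 with an estimated correlation). Of 17 stellate cell and matrix genes 5 rose and 2 fell (8 higher and 2 lower adjusted over the list alone). The stellate cell list had a median of 0.27 (slide-blocked 0.26, positive on 4 of 5 slides) and passed camera (adjusted p = 0.0111, but adjusted p = 0.287 with an estimated correlation). The basement membrane collagen gene Col4a1 rose by 0.73 ± 0.12 (n = 5 and 4) and the protease inhibitor gene Timp1 by 0.41 ± 0.10. In Cy5 alone Col4a1 and Timp1 did not pass (adjusted p = 0.0993 and 0.129). The probes of Acta2 (-0.73 to 0.15) disagreed in sign. In all, 1319 of 17534 genes rose and 1422 fell, 173 and 153 by at least 2-fold. The total of 2741 was 2449 with the slide as a block, 2188 of them shared, 1374 with median centring (61.4% higher against 48.1%) and 1458 in Cy5 alone (27.8% higher).

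**Figure D2:**
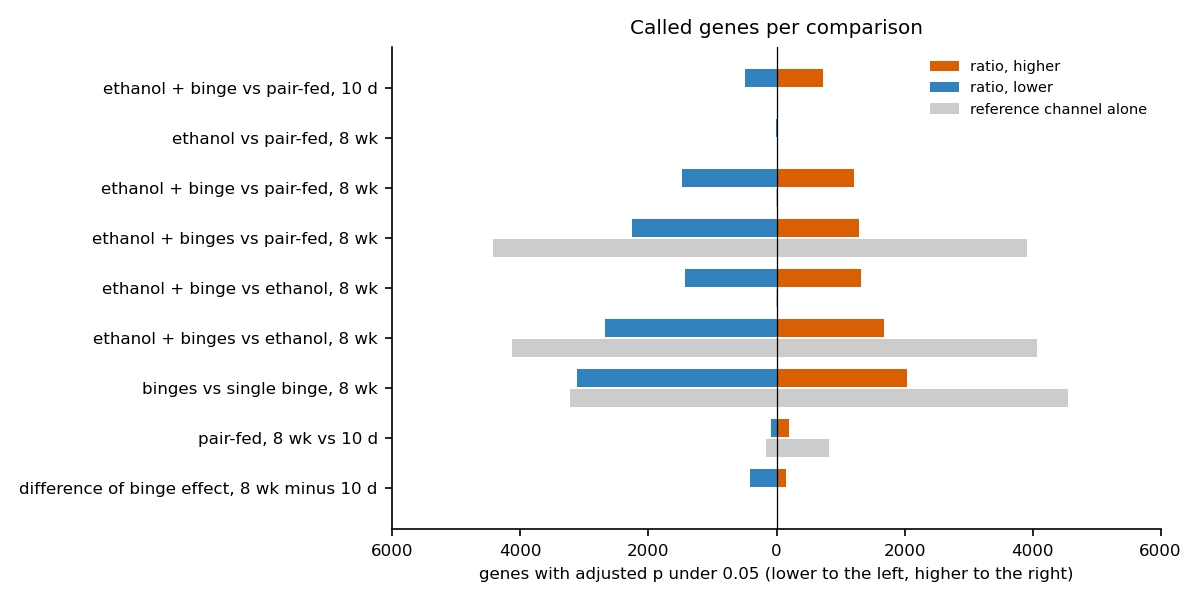
Number of genes with adjusted p under 0.05 in each of the 9 comparisons, higher and lower, beside the number called in the same fit of the Cy3 reference alone. The reference alone gave at most 1 gene where the groups shared a scan and 8334 for multiple binges against 8-week pair-feeding.

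**Figure D3:**
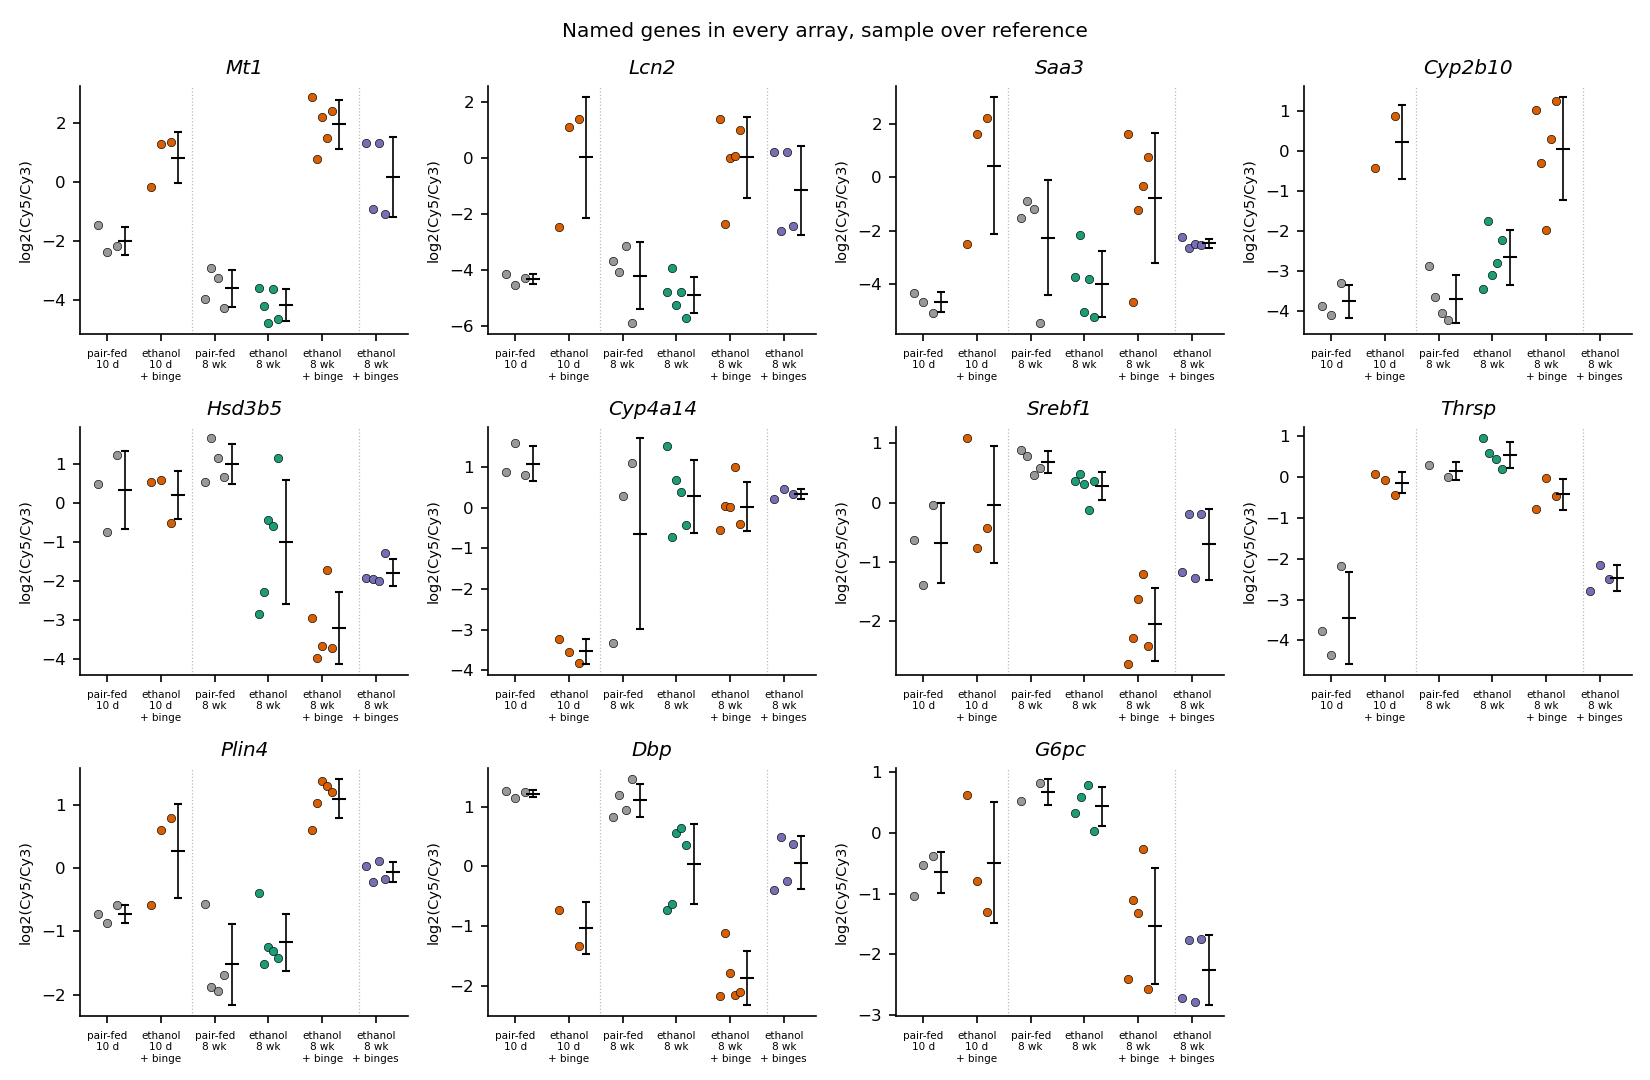
Log2 Cy5/Cy3 of 11 named genes by group, with points for arrays that measured the gene, bars for the group mean with SD, and dotted lines between scans. Mt1 rose by 5.55 and Hsd3b5 fell by 4.20 after 8 weeks of ethanol with 1 binge against 8-week pair-feeding.

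The comparison of 8 weeks of ethanol plus multiple binges with 8-week pair-feeding (n = 4 and 4) asked what repeated binges changed. Mt1, Mt2, the glutathione transferase gene Gstm3, Cyp2b9 and Lcn2 were higher, and G6pc, Hsd3b5 and Thrsp were lower. The multiple-binge arrays formed a scan of their own, so group and scan cannot be told apart in any comparison of this group. Its 4 arrays formed 2 pairs, replicates 1 and 3 at r = 0.651 over all genes and 2 and 4 at 0.784, against 0.433 to 0.586 for other pairs. The labels do not state whether the arrays of a pair came from separate animals. If they did not, the SEs and p-values of this group are too small. The difference in Cy5 alone and that of the Cy3 reference are given in parentheses. Mt1 rose by 3.77 ± 0.52 (log2 fold change ± SE, adjusted p = 7.87e-05, Cy5 2.45, Cy3 -0.88) and Mt2 by 3.16 ± 0.58 (n = 4 and 3, Cy5 2.99, Cy3 0.35). Lcn2 rose by 3.04 ± 0.82 (adjusted p = 0.0111, Cy5 2.69, Cy3 -0.53) and Gstm3 by 3.61 ± 0.64 (n = 4 and 2, Cy5 4.04, Cy3 0.44). Cyp2b9 rose by 3.32 ± 0.48 (n = 3 and 4, Cy5 6.09, Cy3 2.57). G6pc fell by 2.93 ± 0.52 (n = 4 and 2, Cy5 -2.25, Cy3 0.61) and Hsd3b5 fell by 2.79 ± 0.61 (Cy5 -4.79, Cy3 -2.32). Hsd3b5 was well above background in Cy5 on 1 of 4 multiple-binge arrays, so the size of its fall is uncertain. Thrsp fell by 2.63 ± 0.42 (n = 3 and 2, Cy5 -3.49, Cy3 -0.29). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 2.23 ± 0.52 (n = 3 and 4, Cy5 -0.88, Cy3 1.21). It did not pass in Cy5 alone (adjusted p = 0.133) and was at -3.10 without multiple-binge replicate 4. The complement factor D gene Cfd fell by 2.21 ± 0.44 (Cy5 -2.37, Cy3 -0.42) and the hepcidin gene Hamp2 fell by 2.14 ± 0.40 (Cy5 -1.76, Cy3 0.56).

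Of 15 antioxidant and glutathione genes 10 rose (11 higher adjusted over the list alone). The antioxidant list had a median of 1.14 in the ratio and 1.89 in Cy5 alone and passed camera (adjusted p = 9.73e-09, but adjusted p = 0.089 with an estimated correlation). Of 10 xenobiotic metabolism genes 6 rose (8 higher adjusted over the list alone). The xenobiotic list had a median of 1.36 in the ratio and 1.67 in Cy5 alone and passed camera (adjusted p = 9.16e-05, but adjusted p = 0.265 with an estimated correlation). Cyp2c29 rose by 2.14 ± 0.30 (n = 4 and 3, Cy5 1.68, Cy3 -0.07). Of 17 acute phase genes 6 rose (7 higher adjusted over the list alone). The acute phase list had a median of 0.99 in the ratio and 0.25 in Cy5 alone and passed camera (adjusted p = 0.00222, but adjusted p = 0.563 with an estimated correlation). Cd14 rose by 1.90 ± 0.34 (Cy5 1.12, Cy3 -0.90). Of 12 female-predominant liver genes 7 rose (7 higher and 1 lower adjusted over the list alone). The female-predominant list had a median of 0.56 in the ratio and 1.19 in Cy5 alone and passed camera (adjusted p = 0.00295, but adjusted p = 0.265 with an estimated correlation). Of 15 genes of fatty acid and triglyceride synthesis 5 fell (5 lower adjusted over the list alone). The fatty acid synthesis list had a median of -0.19 in the ratio and -0.58 in Cy5 alone and passed camera (adjusted p = 0.0308, but adjusted p = 0.533 with an estimated correlation). In Cy5 alone Fmo2, Mlxipl and Me1 reversed. The fatty acid synthase gene Fasn fell by 1.71 ± 0.41 (Cy5 -2.68, Cy3 -0.99) and Srebf1 fell by 1.38 ± 0.35 (Cy5 -3.17, Cy3 -1.85). Of 19 lipid droplet protein and lipase genes 3 rose (3 higher adjusted over the list alone). The lipid droplet list had a median of 0.23 in the ratio and 0.18 in Cy5 alone and passed camera (adjusted p = 0.0144, but adjusted p = 0.479 with an estimated correlation). Plin4 rose by 1.45 ± 0.28 (Cy5 1.05, Cy3 -0.48). In all, 1291 of 17087 genes rose and 2257 fell, 75 and 202 by at least 2-fold. Of these 3548 genes 2728 had the same sign in Cy5 alone, and the Cy3 reference alone gave 8334 called genes. Of the calls 36.4% were higher, against 51.3% with the scanner software's log ratio, and the total was 2187 without pair-fed replicate 2 and 7953 in Cy5 alone (49.8% higher).

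The comparison of multiple binges with 8 weeks of ethanol alone (n = 4 and 5) asked what repeated binges added to the long diet. Mt1, Mt2 and Lcn2 were higher, and Thrsp, G6pc and Cfd were lower. Mt1 rose by 4.34 ± 0.49 (log2 fold change ± SE, adjusted p = 1.45e-05, Cy5 3.21, Cy3 -0.80) and Mt2 by 3.69 ± 0.51 (Cy5 3.61, Cy3 0.24). Lcn2 rose by 3.73 ± 0.78 (adjusted p = 0.00143, Cy5 3.34, Cy3 -0.43). Thrsp fell by 3.02 ± 0.35 (n = 3 and 4, Cy5 -3.51, Cy3 0.03), G6pc fell by 2.69 ± 0.43 (n = 4 and 4, Cy5 -1.69, Cy3 0.92) and Cfd fell by 2.58 ± 0.42 (Cy5 -2.58, Cy3 -0.36). Of 18 acute phase genes 8 rose (10 higher adjusted over the list alone). The acute phase list had a median of 1.36 in the ratio and 0.99 in Cy5 alone and passed camera (adjusted p = 8.4e-06, but adjusted p = 0.427 with an estimated correlation). The serum amyloid P gene Apcs rose by 1.95 ± 0.43 (Cy5 1.35, Cy3 -0.59). Of 15 antioxidant and glutathione genes 6 rose (6 higher adjusted over the list alone). The antioxidant list had a median of 0.57 in the ratio and 1.85 in Cy5 alone and passed camera (adjusted p = 0.000519, but adjusted p = 0.265 with an estimated correlation). Of 14 neutrophil markers 1 rose and 6 fell (1 higher and 6 lower adjusted over the list alone). The neutrophil list had a median of -0.23 in the ratio and -0.49 in Cy5 alone and passed camera (adjusted p = 0.0329, but adjusted p = 0.386 with an estimated correlation). Camp, an antimicrobial peptide gene, fell by 0.79 ± 0.13 (Cy5 -0.21, Cy3 0.53) and did not pass in Cy5 alone (adjusted p = 0.559). The probes of Itgam (-0.95 and 0.31) and Fpr2 (-0.83 and 0.17) disagreed in sign, and Retnlg, S100a9 and Socs3 reversed in Cy5 alone. In all, 1683 of 17177 genes rose and 2675 fell, 66 and 231 by at least 2-fold. Of these 4358 genes 3428 had the same sign in Cy5 alone, and the Cy3 reference alone gave 8204 called genes. Of the calls 38.6% were higher, against 54.1% with the scanner software's log ratio, and the total was 8220 in Cy5 alone (52.2% higher).

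The comparison of multiple binges with a single binge after 8 weeks of ethanol (n = 4 and 5) asked whether repetition changed the response. Keg1 was higher after multiple binges, by 2.17 ± 0.39 (log2 fold change ± SE, adjusted p = 0.000354, Cy5 1.23, Cy3 -1.17), as were Apol7a by 2.01 ± 0.25 (Cy5 0.86, Cy3 -1.20) and the uridine phosphorylase gene Upp2 by 2.11 ± 0.59 (n = 2 and 4, Cy5 1.12, Cy3 -1.02). Lpin1, a phosphatidate phosphatase of triglyceride synthesis, fell by 2.38 ± 0.49 (adjusted p = 0.00129, Cy5 -2.46, Cy3 0.02). The TWEAK receptor gene Tnfrsf12a fell by 2.28 ± 0.27 (n = 2 and 5, Cy5 -1.53, Cy3 0.80), and Retreg1, a receptor for autophagy of the endoplasmic reticulum, fell by 2.49 ± 0.36 (n = 2 and 4, Cy5 -0.47, Cy3 2.13). Of 13 gluconeogenesis, fasting and glucocorticoid genes 5 fell (7 lower adjusted over the list alone). The gluconeogenesis and fasting list had a median of -0.50 in the ratio and -0.52 in Cy5 alone and passed camera (adjusted p = 0.0111, but adjusted p = 0.313 with an estimated correlation). Cdkn1a fell by 2.23 ± 0.54 (Cy5 -2.02, Cy3 0.31) and Fkbp5 fell by 0.89 ± 0.19 (n = 3 and 5, Cy5 -0.61, Cy3 0.22). On multiple-binge replicates 1 to 4 Cdkn1a lay at 0.37, -2.59, 0.50 and -2.42 and Lpin1 at -0.52, -3.49, -0.43 and -3.17, so replicates 2 and 4 carry most of both falls. Of 16 hepatocyte function genes 6 rose (9 higher adjusted over the list alone). The hepatocyte list had a median of 0.36 in the ratio and 0.50 in Cy5 alone and passed camera (adjusted p = 0.019, but adjusted p = 0.332 with an estimated correlation). Of 12 bile acid genes 5 rose (5 higher adjusted over the list alone). The bile acid list had a median of 0.35 in the ratio and 0.83 in Cy5 alone and passed camera (adjusted p = 0.007, but adjusted p = 0.287 with an estimated correlation). Of 15 neutrophil markers 1 rose and 7 fell (1 higher and 8 lower adjusted over the list alone). The neutrophil list had a median of -0.45 in the ratio and -0.52 in Cy5 alone and passed camera (adjusted p = 0.0026, but adjusted p = 0.265 with an estimated correlation). Among the neutrophil markers Camp fell by 0.78 ± 0.13 (Cy5 -0.00, Cy3 0.72), and the probes of Itgam (-1.18 and 0.25) and Fpr2 (-0.89 and 0.10) disagreed in sign. In Cy5 alone Upp2, Retreg1, Fkbp5 and Camp did not pass (adjusted p between 0.102 and 0.997). In all, 2037 of 17251 genes rose and 3124 fell, 70 and 336 by at least 2-fold. Of these 5161 genes 3995 had the same sign in Cy5 alone, and the Cy3 reference alone gave 7773 called genes. Of the calls 39.5% were higher, against 55.4% with the scanner software's log ratio and 29.3% with median centring, and the total was 3386 without multiple-binge replicate 4 and 7994 in Cy5 alone (59.9% higher).

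**Figure D4:**
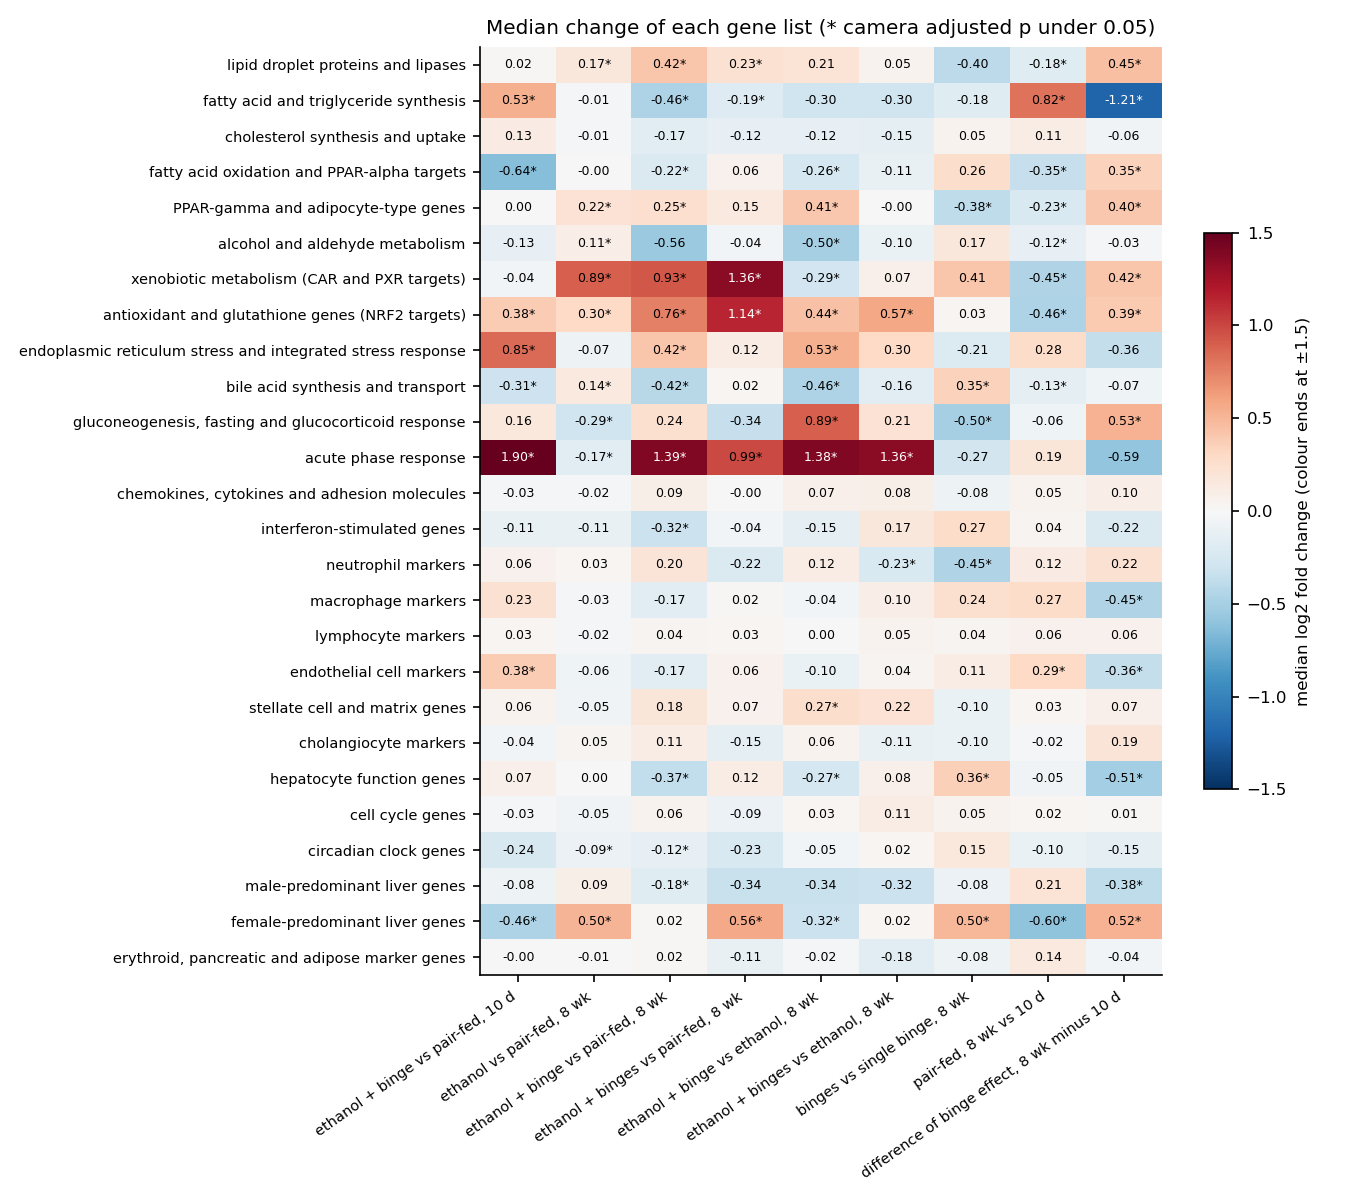
Median log2 fold change of each of the 26 gene lists in each comparison, as a heat map, with an asterisk where camera's adjusted p with its preset correlation was under 0.05. None of the 80 asterisks holds with an estimated correlation.

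The comparison of 8-week with 10-day pair-feeding (n = 4 and 3) asked how the control groups differed, with the groups in different scans. Thrsp rose by 3.59 ± 0.42 (log2 fold change ± SE, n = 2 and 3, adjusted p = 0.00155, Cy5 4.34, Cy3 0.48) and was at 4.22 without 10-day replicate 3. A further 7 named genes passed, namely Cyp2c70 (2.65 ± 0.62, n = 2 and 3), Fasn (1.91 ± 0.44), Acacb (1.23 ± 0.29), Cyp4a31 (-1.27 ± 0.30, well above background in Cy5 on 3 of 4 8-week arrays), the methyltransferase gene Bhmt (-1.21 ± 0.22), Abhd2 (-1.14 ± 0.21) and the acyl-CoA dehydrogenase gene Acadl (-0.48 ± 0.11). Each of the 7 lost its call without 10-day pair-fed replicate 2 (adjusted p between 0.0743 and 0.157). Some of these 7 calls were also lost without 8-week replicates 1, 2 or 3 (highest adjusted p = 0.0798, 0.105 and 0.0534). Some were lost without 10-day replicates 1 or 3 (0.117 and 0.0882). Of 17 genes of fatty acid and triglyceride synthesis 4 rose (6 higher adjusted over the list alone). The fatty acid synthesis list had a median of 0.82 in the ratio and 1.66 in Cy5 alone and passed camera (adjusted p = 1.41e-05, but adjusted p = 0.265 with an estimated correlation). Of 20 genes of fatty acid oxidation and PPAR-alpha 1 fell (1 higher and 4 lower adjusted over the list alone). The fatty acid oxidation list had a median of -0.35 in the ratio and -0.16 in Cy5 alone and passed camera (adjusted p = 5.93e-05, but adjusted p = 0.361 with an estimated correlation). Of 12 female-predominant liver genes 1 fell (6 lower adjusted over the list alone). The female-predominant list had a median of -0.60 in the ratio and -0.68 in Cy5 alone and passed camera (adjusted p = 4.53e-07, but adjusted p = 0.089 with an estimated correlation). Of 12 endothelial cell markers 2 rose (6 higher adjusted over the list alone). The endothelial list had a median of 0.29 in the ratio and 0.48 in Cy5 alone and passed camera (adjusted p = 0.000524, but adjusted p = 0.313 with an estimated correlation). In all, 198 of 17232 genes rose and 82 fell, 45 and 5 by at least 2-fold. Of these 280 genes 277 had the same sign in Cy5 alone, and the Cy3 reference alone gave 983 called genes. Of the calls 70.7% were higher, against 97.9% with median centring, and the total was 1660 in Cy5 alone, 816 with array weights and 813 with the replicate number as a block. Without 8-week pair-fed replicates 1, 2, 3 and 4 it was 185, 55, 89 and 498, and without 10-day replicates 1, 2 and 3 it was 38, 22 and 135.

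The last comparison asked whether the effect of ethanol plus a binge differed with the length of feeding. It took the 8-week effect minus the 10-day effect, each against its own pair-fed group within its own scan (n = 5 and 4 after 8 weeks, 3 and 3 after 10 days). The omega-hydroxylase gene Cyp4a14 differed by 5.29 ± 0.96 (log2 difference ± SE, n = 5 and 3 after 8 weeks, adjusted p = 0.00206, slide-blocked 5.39) and Cyp4a31 by 3.47 ± 0.42 (adjusted p = 4.28e-05, slide-blocked 3.78). Cyp4a14 differed by 3.95 without 8-week pair-fed replicate 2, the lowest of its group, and by 6.16 without replicate 4. Srebf1 differed by -3.37 ± 0.53 (adjusted p = 0.000348, slide-blocked -2.76). Thrsp differed by -3.87 ± 0.56 (adjusted p = 0.000452, n = 3 and 2 after 8 weeks), and by -3.59 (adjusted p = 0.089) with the slide as a block and -4.50 without 10-day pair-fed replicate 3. Slc22a7, an organic anion transporter gene, differed by -3.42 ± 0.39 (adjusted p = 4.28e-05, slide-blocked -3.23). The endothelial gene Fcgr2b differed by -1.81 ± 0.27 (adjusted p = 0.000173, slide-blocked -1.85).

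Of 17 genes of fatty acid and triglyceride synthesis 1 had a higher effect after 8 weeks and 5 had a lower one (1 higher and 6 lower adjusted over the list alone). The fatty acid synthesis list had a median of -1.21 (slide-blocked -0.57) and passed camera (adjusted p = 1.5e-05, but adjusted p = 0.265 with an estimated correlation). Of 19 genes of fatty acid oxidation and PPAR-alpha 2 had a higher effect after 8 weeks (3 higher and 1 lower adjusted over the list alone). The fatty acid oxidation list had a median of 0.35 (slide-blocked 0.43) and passed camera (adjusted p = 0.00213, but adjusted p = 0.479 with an estimated correlation). Of 19 lipid droplet protein and lipase genes 4 had a higher effect after 8 weeks (4 higher adjusted over the list alone). The lipid droplet list had a median of 0.45 (slide-blocked 0.46) and passed camera (adjusted p = 0.0012, but adjusted p = 0.332 with an estimated correlation). Of 12 endothelial cell markers 5 had a lower effect after 8 weeks (1 higher and 6 lower adjusted over the list alone). The endothelial list had a median of -0.36 (slide-blocked -0.36) and passed camera (adjusted p = 0.00145, but adjusted p = 0.332 with an estimated correlation). Of 13 hepatocyte function genes 3 had a lower effect after 8 weeks (1 higher and 5 lower adjusted over the list alone). The hepatocyte list had a median of -0.51 (slide-blocked -0.47) and passed camera (adjusted p = 0.00932, but adjusted p = 0.265 with an estimated correlation). Of 11 female-predominant liver genes 2 had a higher effect after 8 weeks (2 higher adjusted over the list alone). The female-predominant list had a median of 0.52 (slide-blocked 0.72) and passed camera (adjusted p = 0.000279, but adjusted p = 0.234 with an estimated correlation). In all, 152 of 17116 genes had a higher and 412 a lower effect after 8 weeks. The total of 564 was 178 with the slide as a block, 171 of them shared, 177 with median centring, 296 in Cy5 alone (8.11% higher against 27.0%) and 337 without 10-day pair-fed replicate 2.

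The 10-day and 8-week comparisons of ethanol plus a binge with pair-feeding share no arrays. Of 17116 genes tested in both, 238 rose in both, against 49.1 expected from independent lists, and 224 fell in both, against 40.3 expected. A further 44 passed in opposite directions. The fold changes correlated across genes at r = 0.375 and rho = 0.269, and genes are not independent replicates. With a change of at least 2-fold, 37 rose and 27 fell in both.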

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

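The tests on other splits of the arrays, except those of the interaction, and the test of the normalization behind the fatty acid synthesis genes were written before their results were seen, and the other tests weighed here were chosen afterwards.

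The effect of ethanol plus a binge differed between 8 weeks and 10 days in 564 genes by the test of the interaction. The omega-hydroxylase genes Cyp4a14 and Cyp4a31 and the apolipoprotein gene Apoa4 had effects higher by 5.29, 3.47 and 3.36 (log2) after 8 weeks. Cyp4a14 fell by 4.62 ± 0.72 after 10 days, and its difference of 0.67 ± 0.64 after 8 weeks did not pass (adjusted p = 0.569). That value rests on 8-week pair-fed arrays at -3.32, 0.28 and 1.099 (log2 Cy5/Cy3), and without replicate 2, the lowest of them, the difference between the effects was 3.95 (adjusted p = 0.00073). The lipogenic gene Thrsp, the bile acid gene Cyp2c70 and the transporter gene Slc22a7 differed by -3.87, -3.57 and -3.42. Between the pair-fed groups Thrsp and Cyp2c70 differed by 3.59 and 2.65, the opposite way. After 8 weeks Apoa4 and Cyp2c70 were measured on 5 and 2 arrays, and Thrsp on 3 and 2. With the slide as a block the count was 178, and Apoa4 (1.63, adjusted p = 0.475), Thrsp and Cyp2c70 (adjusted p = 0.0766) no longer passed. The Apoa4 call was also lost in Cy5 alone (adjusted p = 0.077) and without each of 8 arrays in turn (highest adjusted p = 0.123).

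Single arrays stood apart within their group for 11 of 335 pairs of a named gene and a group, where chance alone would give about 16.75 at 1 in 20. Groups with under 4 values of a gene, both 10-day groups among them, were not scanned. In the 8-week ethanol group these were Cd14 at -1.46 (log2 Cy5/Cy3) on replicate 5 and Srebf1 at -0.13 on replicate 4. In the single-binge group Abhd5 was at 0.46 on replicate 5, Eng at -0.81 and Retreg1 at 1.83 on replicate 1, and Upp2 at -3.52 on replicate 3. In the 8-week pair-fed group Abhd5 was at -0.62, Gclc at 0.39 and Me1 at 0.74 on replicate 1, and Hadhb at 0.090 on replicate 2. In the multiple-binge group Hsd3b5 was at -1.27 on replicate 4.

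The Cy3 reference, fitted alone only as a check, differed between scans. It gave 8334, 8204 and 7773 called genes for multiple binges against 8-week pair-feeding, 8 weeks of ethanol and a single binge, and 983 between the pair-fed groups. Hsd3b5 had a mean log2 Cy3 intensity of 10.41, 8.36 and 8.17 in scans 1, 2 and 3, Srebf1 one of 13.29, 11.59 and 11.64, and Cyp4a14 one of 12.32, 15.32 and 14.21.

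The first pattern weighed is the 3548 calls of multiple binges against 8-week pair-feeding, with Mt1 and Lcn2 higher and Thrsp lower. A difference between scans in the reference is a candidate cause of part of them, since the reference alone gave 8334 called genes. The normalization may set the balance of directions, since 51.3% of calls were higher with the scanner software's log ratio, against 36.4%. The reference is argued against as the whole cause for Mt1, Lcn2 and Thrsp, since Cy3 gave at most 0.234 of their ratio difference. A part stays open for Mt1 (ratio 3.77, Cy5 2.45). The reference stays open for the rest of the calls, as does the normalization. Repeated binges remain open and untested, as group and scan coincide.

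The second pattern is the spread of Cidec, Mt1 and Lcn2 within the multiple-binge group. Replicates 1 to 4 had Cidec at 0.74, -1.24, 0.81 and -1.10, Mt1 at 1.33, -0.91, 1.33 and -1.08, and Lcn2 at 0.22, -2.61, 0.20 and -2.43. Over all genes replicates 1 and 3, and 2 and 4, also correlated most, so the split reaches beyond these genes. A slide effect is argued against, since at most 0.0027 of the variation of each gene lay between the 2 slides, against 0.333 with no slide effect. The reference is argued against for Cidec and Lcn2, whose SD in Cy3 was 0.163 and 0.195 of that in the ratio. For Mt1, at 0.465, it stays open for a part, and is argued against as the whole cause, since the higher and lower arrays lay 0.978 apart in Cy5 alone, against at most 0.113 within a pair. The design names no biological variable within the group, so no biological explanation was tested. Whether the arrays of a pair came from separate animals is not stated in the labels and was not tested. The 4 arrays may therefore hold fewer independent samples.

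The third pattern is the list of fatty acid and triglyceride synthesis genes, of which 4 of 17 rose, Thrsp and Fasn among them, in 8-week against 10-day pair-feeding, at a list median of 0.82. The reference is argued against, since the list was higher by 0.60 in Cy3, which lowers the ratio. The normalization is argued against, since the lowest median of the ratio over the other normalizations was also 0.82. The feeding state at collection cannot be told apart from the groups, as the list of fasting genes lay at -0.062 with members on both sides. The length of feeding and the age of the mice remain open and untested, and a scan difference in Cy5 coincides with the groups.

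Other splits of the same arrays into groups of the same sizes were fitted in the same way. For 10 days of ethanol plus a binge against pair-feeding the 10 splits are too few for a share under 0.05, and 1 of them, the real one, gave 1211 genes against 0 for the highest other. These splits took no account of the slide. Chance was excluded in that fit where under 0.05 of the splits reached the real count. That held in 1 of 100 splits for 8 weeks of ethanol against pair-feeding (24 genes, highest other 20, a thin margin for a count that was 6 without pair-fed replicate 2) and in 1 of 100 for 8 weeks of ethanol plus a binge against pair-feeding (2691 and 2385). The latter split exchanged all but 1 array, so it nearly mirrors the real one. It held in 1 of 100 for the single binge against 8 weeks of ethanol (2741 and 759).

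For multiple binges, 1 of 35 splits against pair-feeding (3548 genes, highest other 58), 1 of 100 against 8 weeks of ethanol (4358 and 2556) and 1 of 100 against a single binge (5161 and 4881) reached the real count. The highest others against ethanol and against a single binge exchanged all but 1 array. The real splits follow the scan, so a low share excludes chance only if the arrays are independent, and does not exclude the scan. Between the pair-fed groups 2 of 35 splits reached 280 genes, with 343 for the other one, which exchanged all but 1 array, so chance was not excluded. For the interaction the effect shared by both lengths of feeding was taken out of each gene first, since exchanged labels would otherwise carry it. Then 1 of 100 splits, the real one, reached 564 genes, with 407 for the highest other, so chance was excluded in the fit without the slide. That other split exchanged all but 1 array. In the slide-blocked fit labels were exchanged within slides, and 2 of 64 exchanges reached 178 genes. They were the real one and one with 180 that exchanged all shared slides but 1, so the share excludes chance, although the real count was not the highest.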

How the results depend on the processing

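Alternatives were chosen beforehand, except where stated above. The 324 values of named genes had 8540 under the alternatives. Of these 7847 kept direction and side of the threshold, 414 no longer passed, 262 passed only then and 17 reversed. Of the 7847, 324 with average intensities normalized and 217 with the scan block could not have changed. The cause of a change was not tested unless it is given.

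Median centring gave 403 called genes for 10 days of ethanol plus a binge (1211), 12 for 8 weeks of ethanol (24), 1279 for 8 weeks plus a binge (2691), 1374 for the binge added to ethanol (2741) and 177 for the interaction (564). It shifted the median of all genes to -0.117 (from -0.0127) for multiple binges against pair-feeding and to -0.141 (from -0.0150) against a single binge. The scanner software's log ratio gave 12 genes for 8 weeks of ethanol. The deposited log2 values gave 14, and 51.6% to 56.5% higher calls for the comparisons of multiple binges.

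Cy5 alone gave 306 genes for 10 days plus a binge, 1458 for the binge added to ethanol and 296 for the interaction, where it moved the median of all genes to -0.103 (from 0.0216). It gave 7953, 8220 and 7994 for multiple binges against pair-feeding, ethanol and a single binge, with 49.8%, 52.2% and 59.9% higher, and 1660 for the pair-fed groups. Its calls for 8 weeks of ethanol were 17.4% higher (41.7%) and for 8 weeks plus a binge 18.2% (45.3%). In Cy5 alone Acss3 (-0.093) and Adh1 (-0.12) reversed for 8 weeks plus a binge, Fmo2 (0.56), Mlxipl (0.12) and Me1 (0.074) for multiple binges against pair-feeding, Socs3 (-0.24), Retnlg (0.15) and S100a9 (-0.40) against ethanol, Foxo1 (0.37) against a single binge, and Cidec (0.11) between the pair-fed groups. With the mean of its probes Cyp2b13 reversed, to 0.45 between the pair-fed groups and -0.76 in the interaction.

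The slide as a block gave 555 genes for 10 days plus a binge and 178 for the interaction, with fewer arrays on slides that hold both groups, and as a random block (correlation 0.118) 43 for 8 weeks of ethanol. The replicate block gave 11 for 8 weeks of ethanol, where Cidec was at -0.0039, and 813 for the pair-fed groups. A fit of the compared groups alone gave 1731 for 8 weeks plus a binge. Array weights gave 1872 for 10 days plus a binge, 93 for 8 weeks of ethanol and 816 for the pair-fed groups. At least 2-fold, 64 genes were shared between 10 days and 8 weeks plus a binge (462). Normalization of average intensities between arrays left the ratios as they were, and the scan as a block gave no value for comparisons across scans.

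With an estimated correlation camera called 0 of 234 lists (80 at the preset, 84 by fry). Of the 80, 77 kept the sign of their median under every scaling, and 3 in the comparison of the pair-fed groups reversed in Cy5 alone.

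Leaving out 1 array at a time gave 6 to 36 genes for 8 weeks of ethanol, 590 to 1228 for 10 days plus a binge, 2187 to 3640 for multiple binges against pair-feeding, 3386 to 5634 against a single binge, 22 to 498 for the pair-fed groups and 337 to 712 for the interaction. Cidec ranged from -0.25 to 0.475 for 8 weeks of ethanol and from -0.073 to 1.83 for 10 days plus a binge. The share of probes well above background in Cy5 limits what dim genes can show.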

Other observations

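The gene lists described here were fixed beforehand, and the single genes named were chosen after their values were seen, with values not recomputed under the alternatives. No further hypothesis was tested. Genes of cholesterol synthesis and uptake fell in 3 of 23 cases after 8 weeks of ethanol plus a binge against pair-feeding (3 adjusted over the list alone), at a list median of -0.17 (camera, adjusted p = 0.0852). Insig1, which restrains sterol synthesis, fell by 1.13 ± 0.22 (log2 fold change ± SE, limma, adjusted p = 0.000774, n = 5 and 4). Against 8 weeks of ethanol alone Insig1 fell by 1.30 ± 0.21. After 10 days plus a binge it fell by 1.12 ± 0.27. Among chemokines, cytokines and adhesion molecules 1 of 19 rose and 3 fell after 8 weeks plus a binge against pair-feeding (1 and 3 adjusted over the list alone), at a median of 0.09 (camera, adjusted p = 0.931). Cxcl1, which draws neutrophils, rose by 1.08 ± 0.35 (adjusted p = 0.0399) and the interferon-induced Cxcl10 fell by 0.57 ± 0.13 (adjusted p = 0.00329).

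Macrophage markers moved in both directions after 8 weeks of ethanol plus a binge against pair-feeding, with 1 of 14 higher and 2 lower (1 and 2 adjusted over the list alone), at a median of -0.17 (camera, adjusted p = 0.231). The Kupffer cell gene Cd5l fell by 0.77 ± 0.15 (adjusted p = 0.00117) and Adgre1, which encodes F4/80, fell by 0.68 ± 0.17 (adjusted p = 0.00789), while the haemoglobin receptor gene Cd163 rose by 0.77 ± 0.20 (adjusted p = 0.0087). Lymphocyte markers rose in 2 of 12 cases after 10 days of ethanol plus a binge (2 adjusted over the list alone), at a median of 0.03 (camera, adjusted p = 0.455), with the T cell receptor gene Cd3g at 0.98 ± 0.22 and the cytotoxic granule gene Nkg7 at 0.75 ± 0.17. Cholangiocyte markers fell in 1 of 10 cases in that comparison (1 adjusted over the list alone), at a median of -0.04 (camera, adjusted p = 0.379), and that gene was Krt23 at -1.51 ± 0.34. Cell cycle genes rose in 2 of 15 cases when a binge was added to 8 weeks of ethanol (2 adjusted over the list alone), at a median of 0.03 (camera, adjusted p = 0.385), with the cyclin genes Ccne1 at 0.43 ± 0.11 and Ccnb2 at 0.31 ± 0.10. Erythroid, pancreatic and adipose marker genes, written to find cells from outside the liver, fell in 2 of 12 cases after 8 weeks plus a binge (2 adjusted over the list alone), at a median of 0.02 and a mean of -0.13 (camera, adjusted p = 0.764, downward), with the haem synthesis gene Alas2 at -1.22 ± 0.20.

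Within the comparisons of a binge with its own pair-fed group, the genes with at least 2 tested probes included 1 of 742 called genes with probes called in opposite directions after 10 days, and 16 of 1611 after 8 weeks. For multiple binges against pair-feeding it was 63 of 1970.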
